A study of Homo sapiens with 6 samples.

How the data were processed

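RNA was extracted from IMR32 neuroblastoma cells with a column kit, polyA-selected and made into libraries with an Illumina-compatible kit, per the labels' protocols. The authors deposited 1 table of TPM values with a row per gene symbol and a column per library. Per the submitters' processing notes, reads were handled with bcl2fastq and Salmon 0.7.2 and the build was GRCh38. The transcript annotation, the Salmon options and the way transcripts were summed to genes are not given in the sources used here. A TPM value divides the reads of a transcript by its length and scales each library to a fixed total. It is a share of the library, so a rise of some genes lowers the values of others. The columns summed to about 972453 to 973696 TPM, under the nominal TPM total, so some transcripts are not in the table analysed here. TPM is not a count and keeps no depth, so the depth per library is unknown. No counting error or detection floor can be given, and the precision rests on the 3 replicates per group.

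Samples were grouped by the treatment in their titles, 3 CBR-470-1 and 3 DMSO. The design, gene lists, test thresholds, rule for named genes and other settings were set before the data were examined. Values were analysed as log2(TPM + 1), for the 13470 rows with a mean of at least 1 TPM over the 6 libraries, with limma 3.58.1 in R 4.3.3 (group as the only factor, empirical Bayes with a variance trend on mean expression) and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. A second threshold asked for an absolute log2 fold change of at least 1. Means, SDs and ratios are of linear TPM, and fold changes are on the log2(TPM + 1) scale. Tests are two-sided. A rank or permutation test of 3 against 3 cannot go below p = 0.1, so single genes were tested only in the model fitted across genes.

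Gene lists, 31 in number, were tested with camera (preset inter-gene correlation of 0.01, variance trend, Benjamini-Hochberg over the 30 lists with at least 3 tested members). Of 494 distinct symbols, 491 were in the table, after matching older symbols, and 424 were tested. Symbols were matched to GENCODE 29 on GRCh38 for coordinates, GC content and length of the longest transcript: 34686 rows by name, 628 through tables of gene synonyms, and 159 not at all. The text names the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 TPM and no overlap between the groups. It also names 14 genes of the NRF2 and glycolysis question, and up to 4 members per list with the largest absolute change. Genes outside this rule are said to be named after their values were seen. Single-gene results for some of the genes this rule takes are not reported here. Of the tested rows, 32 shared all values with another row, 2 of them called.

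The alternatives were pseudocounts of 0.1 and 5 TPM, no filter and a filter of 5 TPM, median centring, quantile normalization, and rescaling without mitochondrially encoded and ribosomal protein genes. Further ones were no variance trend and robust empirical Bayes. Others were the replicate number as a block, each library left out in turn, an adjusted p under 0.01, camera with an estimated correlation, fry, and lists without shared genes. A GC and length correction, which removes from each library a spline trend (5 degrees of freedom) with GC content and log length, was added after a GC trend had been seen. All 10 splits of the 6 libraries into 3 and 3 were refitted. The gene test was tested on simulated data for the CBR-470-1 against DMSO comparison, with 40 genes changed at each of 5 sizes among 13470. It recovered 60% of genes raised by 0.5, 77.5% lowered by 0.5, 92.5% raised by 1, 85% lowered by 1 and 95% raised by 2 on the log2 scale, with 12 false calls. In the list test, 3 of 200 unchanged simulated lists of 20 genes had p under 0.05. The simulated genes varied independently of each other, so this does not cover lists whose members vary together. They also carried no trend with GC content, unlike the real libraries. The 12 false calls are therefore not a rate for the real gene calls.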

Results

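Messenger RNA was measured by polyA-selected RNA sequencing in IMR32 cells, a human neuroblastoma line, after 24 h with 5 µM CBR-470-1 or with the same volume of the DMSO vehicle. Each condition had 3 independent biological replicates, which gave 6 libraries in 2 groups. The deposited table holds TPM values, the length-scaled share of each gene's transcripts in its library, for 35473 gene rows. Its columns summed to between 972453 and 973696 TPM. Rows above 0 numbered from 20020 to 20598 per library. The 10 most abundant rows held 6.39% to 6.46% of the total, and mitochondrially encoded genes held 3.84% to 4.40%. TPM keeps no record of sequencing depth, so the depth behind each value is unknown. The first principal component of the tested genes carried 30.9% of the variance and placed the DMSO libraries between -16.6 and -9.36 and the CBR-470-1 libraries between 7.91 and 15.6. Correlations between libraries across genes ran from 0.989 to 0.991 within a group and from 0.986 to 0.989 between groups.

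The series title names glycolysis and the KEAP1-NRF2 pathway, in which the adaptor KEAP1 holds down the transcription factor NRF2. The comparison asked which transcripts differed after CBR-470-1 and whether NRF2 target genes were among them. The clearest difference was in the NRF2 target genes. NQO1, a quinone reductase and a standard NRF2 target, rose from 4.66 ± 0.817 TPM in DMSO to 66.2 ± 4.59 TPM in CBR-470-1 (SD, n = 3 each), a ratio of 14.2. FTL, the ferritin light chain, rose from 631 ± 21.4 to 1417 ± 27.1 TPM, a ratio of 2.24. ME1, the cytosolic malic enzyme that makes NADPH, rose from 7.35 ± 0.489 to 17.8 ± 0.435 TPM, a ratio of 2.42. HMOX1, which degrades haem, rose from 0.882 ± 0.361 to 3.54 ± 0.863 TPM. The aldo-keto reductase AKR1C3 rose from 0.351 ± 0.138 to 6.89 ± 1.17 TPM. Fold changes below are on the log2(TPM + 1) scale, which understates changes of low genes. In limma they were 3.58 for NQO1 (SE 0.115, adjusted p = 2.67e-05) and 1.17 for FTL (SE 0.0341, adjusted p = 2.67e-05). They were 1.17 for ME1 (SE 0.0721, adjusted p = 0.00126), 1.27 for HMOX1 (SE 0.192, adjusted p = 0.0291) and 2.54 for AKR1C3 (SE 0.150, adjusted p = 0.00118). In GRCh38 with GENCODE 29 gene models, NQO1 (ENSG00000181019.12) spans 69706996 to 69726951 on chromosome 16. FTL (ENSG00000087086.14) spans 48965301 to 48966878 on chromosome 19 and ME1 (ENSG00000065833.8) spans 83210389 to 83431071 on chromosome 6. These values are sums over the transcripts of a gene, so they carry no information on exons or UTRs.

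Of the 42 NRF2 target genes in the list, 31 were abundant enough to test, and 14 of them rose and 0 fell over all genes tested. When adjusted over the list alone, 24 rose and 1 fell. The list was higher as a whole, with a median log2 fold change of 0.54 (camera adjusted p = 4.22e-17, and adjusted p = 0.0166 with an estimated correlation). Besides the 5 genes above, PIR rose from 30.9 ± 1.85 to 62.3 ± 4.01 TPM. GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, rose from 25.3 ± 2.64 to 43.6 ± 1.40 TPM, and TXNRD1, thioredoxin reductase, from 188 ± 7.21 to 293 ± 13.5 TPM. The autophagy receptor SQSTM1 rose from 40.5 ± 2.69 to 65.3 ± 2.76 TPM, and TKT, transketolase of the pentose phosphate pathway, from 273 ± 12.2 to 398 ± 9.17 TPM. The remaining called members, FTH1, PRDX1, TXN and PANX2, were named after their values were seen and had log2 fold changes of 0.46, 0.54, 0.36 and 0.73. The catalytic subunit GCLC (78.4 to 96.9 TPM, adjusted p = 0.0692) and SRXN1 (14.5 to 21.5 TPM, adjusted p = 0.0800) did not pass in limma over all genes. TALDO1, transaldolase, had a log2 fold change of -0.28, did not pass over all genes and was the member that fell when adjusted over the list alone. SLC7A11, at 0.354 and 0.631 TPM, and OSGIN1, at 0.190 and 0.297 TPM in DMSO and CBR-470-1, were too low to test.

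**Figure D1:**
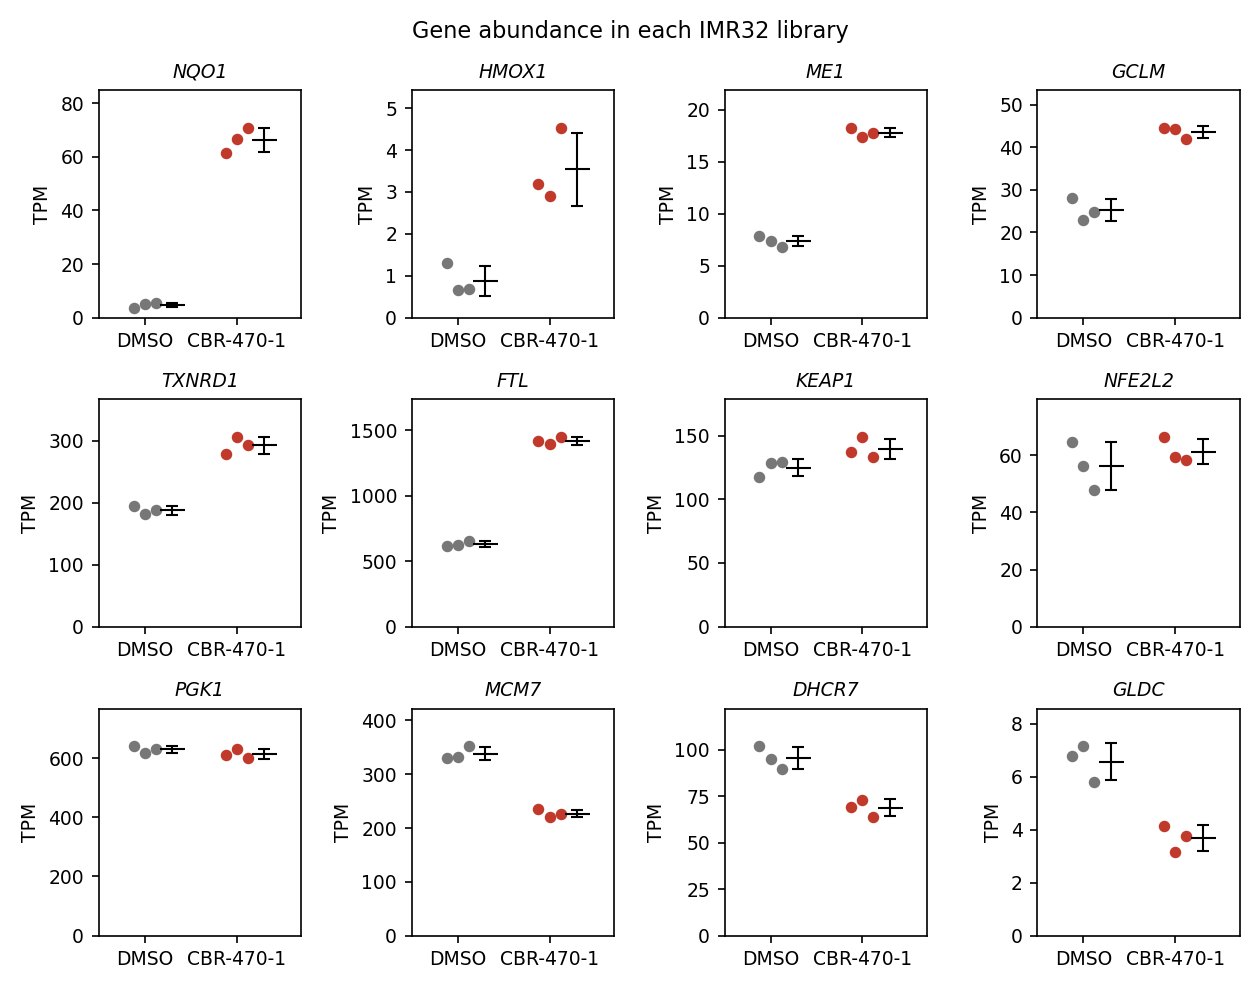
TPM on the y axis, from 0, of 12 genes in the 3 DMSO libraries (grey) and the 3 CBR-470-1 libraries (red), with the group mean and SD in black beside the points. NQO1 lies near 4.66 TPM in DMSO and 66.2 TPM in CBR-470-1, whereas the PGK1 points of both groups overlap, at means of 629 and 614 TPM.

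None of the listed KEAP1-NRF2 pathway components was called. Among them MAFG, which encodes a partner of NRF2, did pass as higher with the GC and length correction (log2 fold change 0.32, limma adjusted p = 0.0292, against 0.29 and 0.0645 without it). Of 12 tested KEAP1-NRF2 pathway components, 0 rose and 0 fell over all genes, and 1 rose when adjusted over the list alone (median log2 fold change 0.13, camera adjusted p = 0.111). KEAP1 stood at 125 ± 6.65 TPM in DMSO and 140 ± 7.96 TPM in CBR-470-1 (limma adjusted p = 0.161), and NFE2L2, which encodes NRF2, at 56.3 ± 8.43 and 61.4 ± 4.33 TPM (limma adjusted p = 0.504). BACH1, a repressor of NRF2 target genes, had a log2 fold change of 0.30 (limma adjusted p = 0.104).

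Glycolysis genes did not move as a group: of 20 tested, 0 passed over all genes and 1 rose when adjusted over the list alone (median log2 fold change -0.03, camera adjusted p = 0.671). PGK1, phosphoglycerate kinase, had 629 ± 10.9 TPM in DMSO and 614 ± 16.1 TPM in CBR-470-1 (limma adjusted p = 0.549). HK1 had a log2 fold change of 0.25 (limma adjusted p = 0.0651) and ALDOA one of 0.14 (limma adjusted p = 0.0846, or 0.0434 with the GC and length correction). Of 10 pentose phosphate and NADPH genes, TKT and ME1 rose, and both are also in the NRF2 list. In this list 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.671). Of 12 methylglyoxal and aldehyde detoxification genes, 0 passed over all genes and 2 rose when adjusted over the list alone (camera adjusted p = 0.671). GLO1, which clears methylglyoxal with glutathione, went from 195 ± 6.62 to 222 ± 6.06 TPM (limma adjusted p = 0.0651). Of 5 MondoA and ChREBP targets, 0 passed over all genes and 1 fell when adjusted over the list alone (camera adjusted p = 0.996). TXNIP was at 56.1 ± 1.15 and 48.2 ± 2.26 TPM (limma adjusted p = 0.0775, or 0.0255 with the GC and length correction).

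The called genes of lipid and serine synthesis were few and all lower, and the calls of their 3 lists were lost with an estimated correlation. Of 23 tested cholesterol synthesis genes, 0 rose and 4 fell over all genes, and 12 fell when adjusted over the list alone. The list was lower (median log2 fold change -0.16, camera adjusted p = 4.28e-09, but adjusted p = 0.175 with an estimated correlation). DHCR7, the last enzyme of one branch to cholesterol, fell from 95.6 ± 6.05 to 68.8 ± 4.51 TPM. FDPS, farnesyl diphosphate synthase, fell from 418 ± 5.92 to 334 ± 8.70 TPM, LSS, lanosterol synthase, from 54.1 ± 1.81 to 43.4 ± 1.42 TPM, and ACAT2 from 181 ± 7.23 to 148 ± 5.54 TPM. Their limma adjusted p-values were 0.0267, 0.0110, 0.0364 and 0.0357. Of 9 fatty acid synthesis genes, 1 fell, the desaturase SCD (log2 fold change -0.25, limma adjusted p = 0.0349). In that list 2 fell when adjusted over the list alone (median -0.12, camera adjusted p = 0.00198, but adjusted p = 0.318 with an estimated correlation). Of 10 serine and one-carbon genes, 1 fell, GLDC of the glycine cleavage system, from 6.56 ± 0.698 to 3.68 ± 0.493 TPM (limma adjusted p = 0.0398), and 6 fell when adjusted over the list alone. The median of that list was -0.15 (camera adjusted p = 3.56e-05, but adjusted p = 0.175 with an estimated correlation), with PHGDH at -0.23, PSPH at -0.31 and PSAT1 at -0.20. None of the latter passed over all genes, but with the GC and length correction all did (limma adjusted p = 0.0375, 0.0435 and 0.0201). When single libraries were left out, which leaves fewer samples, LSS, ACAT2, SCD and GLDC lost their calls in all 6 fits. DHCR7 lost its call in 5 and FDPS in 4.

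DNA replication genes were lower and mitosis genes were not called. Of 21 replication genes, 0 rose and 2 fell over all genes, and 13 fell when adjusted over the list alone. The list was lower (median log2 fold change -0.15, camera adjusted p = 4.92e-09, and adjusted p = 0.0363 with an estimated correlation). MCM7, a subunit of the replicative helicase, fell from 338 ± 11.7 to 227 ± 7.07 TPM (limma log2 fold change -0.57, SE 0.0416, adjusted p = 0.00203). RRM2, a ribonucleotide reductase subunit named after its values were seen, had a log2 fold change of -0.25 (limma adjusted p = 0.0439). CDT1 and CDC45 had -0.39 and -0.33 without passing. Of 20 mitosis genes, 0 passed over all genes or when adjusted over the list alone (median -0.03, camera adjusted p = 0.102), with AURKB at -0.28 (limma adjusted p = 0.127). The mitosis list passed, as lower, without DMSO replicate 3 (camera adjusted p = 0.000780), without CBR-470-1 replicate 2 (camera adjusted p = 0.0311) and with the GC and length correction (camera adjusted p = 0.000661). It also passed with no filter and with median centring. With an estimated correlation it did not pass after the GC and length correction (camera adjusted p = 0.321), where 0 members were called. Of 23 p53 targets, 1 rose, the cell cycle inhibitor CDKN1A, from 36.6 ± 2.42 to 45.8 ± 0.579 TPM (limma adjusted p = 0.0493). When adjusted over the list alone, 7 rose. By that measure 3 of 12 reference genes rose and 2 fell, so this count alone does not set p53 targets apart from them. The p53 list was higher (median 0.18, camera adjusted p = 0.0201, but adjusted p = 0.180 with an estimated correlation and 0.0517 for genes of at least 5 TPM). Of 19 MYC and ribosome biogenesis genes, 1 rose, GNL3 at 0.26, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.671).

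Of 15 adrenergic neuroblastoma identity genes, 0 rose and 2 fell over all genes. These were DBH, which makes noradrenaline, from 12.7 ± 0.683 to 8.51 ± 0.372 TPM (limma adjusted p = 0.0247) and CHGA, chromogranin A, from 365 ± 11.2 to 311 ± 12.3 TPM (limma adjusted p = 0.0468). CHGA lost its call with the GC and length correction, where its log2 fold change shrank from -0.23 (SE 0.0423) to -0.15 (SE 0.0316, adjusted p = 0.0544). The noradrenaline transporter gene SLC6A2 passed there as higher (0.33, adjusted p = 0.0463, against 0.32 and 0.0642 without it). When adjusted over the list alone, 1 rose and 3 fell. The list was lower (median -0.05, camera adjusted p = 0.0201, but adjusted p = 0.505 with an estimated correlation). The call was lost without DMSO replicate 3 (camera adjusted p = 0.0930), with quantile normalization (0.0612) and with the GC and length correction (0.327). Neuronal differentiation genes moved both ways: of 18, 2 rose and 3 fell over all genes, and 5 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.794). The neurofilament gene NEFH and STMN2 rose by 0.48 and 0.38 on the log2 scale, while the neuropeptide gene NPY fell by 0.49, the tubulin gene TUBB3 fell by 0.38 and GAP43, named after its values were seen, fell by 0.36. Of 10 tested mesenchymal and Schwann-like markers, 0 passed over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.794), with VIM at 0.20 and TWIST1 at -0.24. All 11 blood and epithelial markers lay under the minimum of 1 TPM, so 0 were tested.

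Stress and organelle lists showed few calls. Of 20 ATF4 stress response genes, 1 fell, the glutathione-degrading enzyme CHAC1, from 2.44 ± 0.233 to 1.01 ± 0.161 TPM (limma adjusted p = 0.0377). Here 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.343). Of 16 heat shock genes, 1 rose, HSP90AA1 at 0.31, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.596). Of 16 hypoxia genes, 1 rose, EGLN3 at 0.51, and 3 rose when adjusted over the list alone (camera adjusted p = 0.102, or 0.0446 without DMSO replicate 3). Of 14 autophagy and lysosome genes, SQSTM1 and MAP1LC3B rose, and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.102, but 0.0446 without DMSO replicate 3, 0.0440 without CBR-470-1 replicate 3 and 0.0117 with the GC and length correction). Of 20 nuclear-encoded oxidative phosphorylation genes, 1 fell, NDUFV1 of complex I at -0.23 (limma adjusted p = 0.0405). In that list 6 fell when adjusted over the list alone (median -0.04, camera adjusted p = 0.00643, but adjusted p = 0.175 with an estimated correlation and 0.0818 with quantile normalization). No member passed over all genes, or when adjusted over the list alone, among 17 ER unfolded protein response genes (camera adjusted p = 0.864), 9 aminoacyl-tRNA synthetase genes (0.462), 3 metal response genes (0.794), 9 immediate early genes (0.596), 4 inflammatory genes (0.996), 4 interferon genes (0.944), 13 mitochondrially encoded genes (0.596) or 20 ribosomal protein genes (0.111). Of 12 reference genes, 0 passed over all genes, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.596). Passing over the list alone was thus not rare among control genes, so a few such passes do not by themselves mark a changed list. The median, the mean and the direction of the camera test differed in sign for the glycolysis, pentose phosphate, MYC, immediate early, inflammatory and reference lists, none of which was called.

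**Figure D2:**
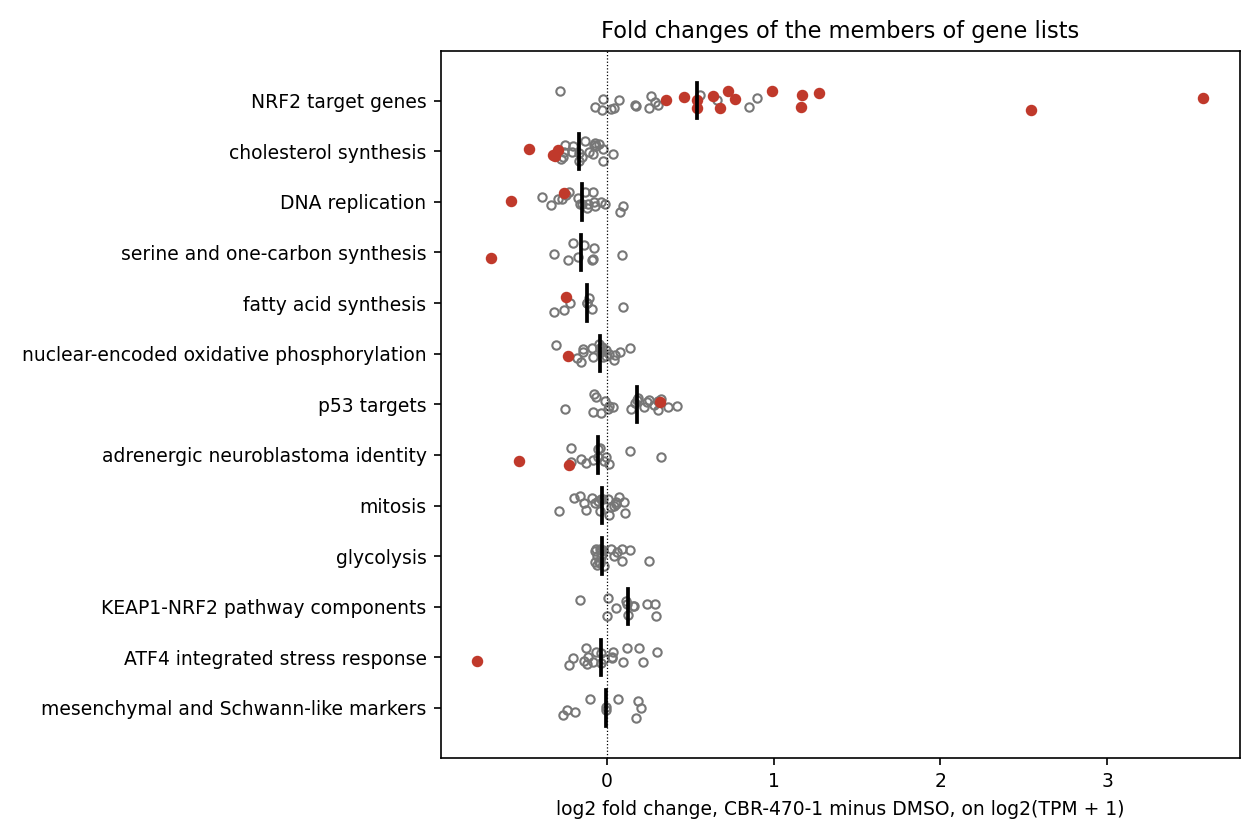
Each point is the log2 fold change (x axis, CBR-470-1 minus DMSO, on log2(TPM + 1)) of a tested member of a gene list (y axis); filled red points passed the limma test over all genes, open grey points did not, and black bars are list medians. The NRF2 target genes have a median of 0.54 and 14 red points, and the cholesterol synthesis and DNA replication lists have medians of -0.16 and -0.15.

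Over all genes, 265 of the 13470 tested passed the limma test, 152 higher and 113 lower in CBR-470-1. Of these, 13 changed by at least 2-fold on the log2(TPM + 1) scale, 7 higher and 6 lower. Beyond the NRF2 targets, the largest increases among genes of at least 5 TPM were in MAP1A, a microtubule-associated protein gene (11.7 ± 0.162 to 20.3 ± 0.155 TPM), CALML4 (14.5 ± 0.706 to 24.8 ± 2.69 TPM) and the long non-coding RNA MALAT1 (76.9 ± 14.7 to 123 ± 4.67 TPM). They were followed by KBTBD8 (4.62 ± 0.558 to 7.89 ± 0.716 TPM) and SYNM, an intermediate filament gene (11.4 ± 0.273 to 18.0 ± 0.820 TPM). With the GC and length correction MALAT1 and KBTBD8 lost their calls, as their log2 fold changes shrank from 0.69 (SE 0.125) to 0.57 (SE 0.118, adjusted p = 0.0552) and from 0.66 (SE 0.108) to 0.56 (SE 0.110, adjusted p = 0.0502). The largest decreases were in SFT2D3 (7.38 ± 0.513 to 3.64 ± 0.489 TPM), LYPD1 (6.70 ± 0.0220 to 3.36 ± 0.476 TPM), C21orf33 (28.5 ± 2.72 to 16.0 ± 1.36 TPM) and GLDC. Next came the linker histone genes H1FX (390.5 ± 44.3 to 246 ± 6.88 TPM) and H1F0 (193 ± 6.08 to 128 ± 1.38 TPM). MXD3, MCM7, MCRIP1, IGFBP5, LHFPL4 and HTR3A, a serotonin receptor subunit gene, completed the 12 decreases, with log2 fold changes between -0.59 and -0.54. The 2-fold set, named after its values were seen where the rule did not reach it, held NQO1, AKR1C3, HMOX1, ME1, FTL, SNORD93 and RN7SL809P on the higher side. On the lower side it held NCAM2, a neural adhesion molecule gene (4.80 ± 0.501 to 1.62 ± 0.672 TPM), GAGE12F and GAGE12G, whose rows were identical and belong to near-identical paralogs. It also held DNAJC19P9, ISCA1P4 and RNA5SP217, which were listed at 0 in every CBR-470-1 library. SNORD93 was listed at 0 in every DMSO library. Short and pseudogene rows of this kind can share reads with other genes and are uncertain.

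The groups did not overlap for 30.2% of the tested genes, against the 10% that chance gives on average for 3 against 3, and 3163 genes had an unadjusted p under 0.05. Genes of a library move together, so the share in a single split can lie far from that average. No share is given for the other splits. Median centring gave 118 higher and 138 lower calls, and the GC and length correction 151 higher and 214 lower, so the balance of directions depended on the scaling. The number of calls also moved with the libraries and filters. It was 81, 36 and 82 without DMSO replicates 1, 2 and 3, and 31, 26 and 18 without CBR-470-1 replicates 1, 2 and 3. It was 82 with no filter, 428 with a mean of at least 5 TPM and 83 with no variance trend. Among the called genes named here, NQO1, FTL, ME1, AKR1C3, PIR, TXNRD1, TKT, SQSTM1, FTH1, PRDX1, MAP1A, MCM7, H1F0 and the tubulin gene TUBA1A, named after its values were seen, passed with any 1 library left out.

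**Figure D3:**
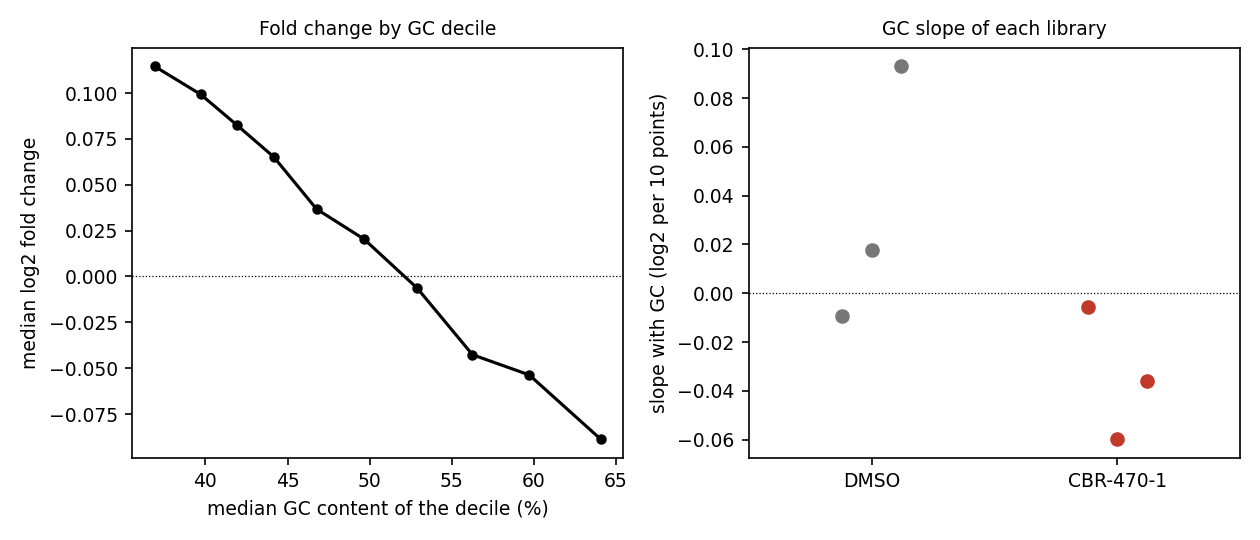
Left, the median log2 fold change (y axis) of tested genes in 10 bins of GC content (x axis, %), which runs from 0.11 in the lowest bin to -0.09 in the highest. Right, the slope of each library's deviations with GC content (y axis, log2 per 10 percentage points) for 3 DMSO and 3 CBR-470-1 libraries, with DMSO replicate 3 at 0.0930.

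Fold changes fell with the GC content of the gene. The higher calls had a median GC content of 43.9% and the lower calls 56.0%, against 48.0% for tested genes that were not called. With each library's trend with GC content and length removed, 210 genes were called in both fits, and of the 8 called lists the adrenergic one was lost. Of the list members, CHGA alone lost its call. Those that gained one over all genes, named in part after their values were seen, were BLVRB, MAFG, ALDOA, BAG3, GADD45A, SLC6A2, NEFM, INA and ATP6V0D1, all higher. PHGDH, PSAT1, PSPH, MTHFD2, ASNS, TXNIP, INSIG1, TMEM97, MCM2, MCM3, MCM4 and MCM6 gained one as lower. This gave 6 lower calls each in the cholesterol and replication lists, 5 in the serine list and 16 higher calls in the NRF2 list.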

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

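The test with the GC and length correction was chosen after the data were seen; the others were planned. No called gene changed sign where it was tested, and no called list reversed. The balance of the calls did: 152 were higher and 113 lower as reported, against 118 and 138 with median centring, 118 and 121 with quantile normalization, and 151 and 214 with the GC and length correction. Higher and lower calls numbered 54 and 28 with no filter, 245 and 183 with at least 5 TPM (fewer genes tested). They numbered 51 and 32 with no variance trend, and 16 and 6 at an adjusted p under 0.01. The 2-fold calls were 4 higher and 0 lower with a pseudocount of 5 TPM, 3 and 0 with at least 5 TPM, 3 lower with no filter and 3 lower with no variance trend. Higher lists numbered 4 with no filter, 1 with at least 5 TPM and 5 with directional fry. With camera's estimated correlation 1 higher and 1 lower remained, and mixed fry, which asks for change in either direction, passed 24. The reference genes were among those 24 (mixed fry adjusted p = 0.0264), so mixed fry did not set changed lists apart from that control. The cause was not tested where no fewer genes or samples were used.

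Lists lost their call as follows. The p53 list had an adjusted p of 0.0517 with at least 5 TPM. With quantile normalization the adrenergic list had 0.0612 and the oxidative phosphorylation list 0.0818, and the adrenergic list had 0.327 with the GC and length correction. With the estimated correlation the adjusted p-values were 0.175 for serine, cholesterol and oxidative phosphorylation genes, 0.318 for fatty acid genes, 0.180 for p53 targets and 0.505 for the adrenergic list. With directional fry, fatty acid genes had 0.0703 and the adrenergic list 0.171. The cause was not tested. Of the lists not called, 3 passed with no filter: mitosis (0.0415), KEAP1-NRF2 components (0.0415) and autophagy (0.0337). With median centring, mitosis (0.0448) and ribosomal proteins (0.0327) passed, and with the GC and length correction, mitosis (0.000661) and autophagy (0.0117). With that correction and an estimated correlation, mitosis (0.321) and autophagy (0.250) did not pass. With directional fry, pentose phosphate and NADPH (0.00720), hypoxia (0.00720) and autophagy (0.0283) passed. The pentose phosphate list had 5 positive and 5 negative fold changes (median -0.03). Its called members TKT and ME1, and SQSTM1 of the autophagy list, are also in the NRF2 list.

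With 1 library left out, which leaves fewer samples, higher calls ranged from 14 to 55 and lower calls from 4 to 30, 2-fold calls from 4 to 11 higher and 0 to 3 lower, and called lists from 2 to 4 higher and 6 to 7 lower. Camera adjusted p-values ranged from 9.04e-18 to 2.24e-14 for NRF2 targets, 2.60e-10 to 1.67e-06 for cholesterol, 1.50e-10 to 7.23e-07 for replication. They ranged from 9.91e-06 to 0.000618 for serine and 0.000576 to 0.00960 for fatty acids. For oxidative phosphorylation they ranged from 0.000801 to 0.0443, with 0.00597 to 0.0493 for p53 targets and 0.00833 to 0.0930 for the adrenergic list, which was lost without DMSO replicate 3. Of the 70 called genes named in the text, 35, 22 and 35 passed without DMSO replicates 1, 2 and 3, and 22, 17 and 14 without CBR-470-1 replicates 1, 2 and 3. The depth is unknown, so what it limits cannot be given.

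The replicate numbers did not pair the libraries. Same-number correlations of deviations from the group means were -0.138, -0.00591 and -0.0318, and 0 of 6 libraries correlated best with their own number. A replicate block, which uses up degrees of freedom, gave 14 higher and 3 lower calls, 16 of them shared with the calls without it, and 0 lower 2-fold calls.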

Other observations

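The families below, the GC and length correction, the paralog and cell cycle tests and the counts over splits were chosen after the results were seen. The families were picked from their called members, so a test of a family as a set decides nothing, and the calls below are those of single genes over all genes tested. Of 11 alpha- and beta-tubulin genes tested, which encode the subunits of microtubules, 7 fell and 0 rose, namely TUBA1A, TUBA1B, TUBA1C, TUBB, TUBB2A, TUBB2B and TUBB3. TUBA1A fell from 1100 ± 16.7 to 865 ± 17.2 TPM and TUBB2B from 324 ± 22.2 to 233 ± 3.62 TPM (SD, n = 3 each). With the GC and length trend removed all 7 kept their calls, which argues against the trend as their whole cause. Of all 113 lower calls 101 were kept, and of all 152 higher calls 109, so keeping calls is not particular to these families. When single libraries were left out, TUBA1A alone passed in all 6 fits, while TUBB3 lost its call in all 6 and TUBA1B and TUBA1C in 5 each. Of 3 linker histone genes, H1F0 and H1FX fell and kept their calls with the trend removed (limma adjusted p = 0.000952 for each). H1F0 also passed with any 1 library left out, but H1FX lost its call in 4 of those 6 fits. HIST1H1C had 13.8 ± 2.02 TPM in DMSO and 17.4 ± 1.01 TPM in CBR-470-1, a log2 fold change of 0.32 that did not pass (limma adjusted p = 0.128).

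Of 35 proteasome subunit genes tested, 4 rose and 0 fell, PSMD12, PSMD1, PSMC2 and PSMD4. PSMD12 rose from 81.3 ± 1.62 to 105 ± 3.20 TPM. With the trend removed 3 kept their calls and PSMC2 lost its call, as its log2 fold change shrank from 0.24 (SE 0.0456) to 0.15 (SE 0.0482, adjusted p = 0.147). When single libraries were left out, PSMD1, PSMC2 and PSMD4 lost their calls in all 6 fits and PSMD12 in 4. The intermediate filament genes looked at were INA, NEFH, NEFL, NEFM, NES, PRPH, SYNM and VIM, not the whole family. Of these 8, NEFH, NES and SYNM rose and 0 fell, and all 3 kept their calls with the trend removed. When single libraries were left out, NES lost its call in all 6 fits and NEFH and SYNM in 2 each. The camera p-values of the families as sets with the trend removed (4.35e-08 for tubulin, 0.0106 for linker histone, 1.37e-07 for proteasome and 1.06e-06 for intermediate filament genes) are tests of picked families and exclude nothing.

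Fold changes fell with GC content (rank correlation across genes -0.351; genes are not independent replicates). Library-to-library GC bias unrelated to treatment is a candidate explanation: 4 of the 10 splits of the libraries, the real one included, gave an absolute correlation as large, and the highest other was 0.465. The trend as the whole cause is argued against for the main lists, whose camera adjusted p-values with it removed were 6.12e-21 for NRF2 targets, 1.31e-11 for cholesterol, 2.56e-10 for replication, 2.88e-06 for serine and 0.000665 for fatty acid synthesis. With an estimated correlation as well, only the NRF2 and replication calls held (adjusted p = 0.0279 each), while cholesterol (0.117), serine and fatty acid synthesis (0.158 each) did not pass, as they did not before the trend was removed. A GC-linked effect of CBR-470-1 stays open.

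DNA replication genes were lower while mitosis genes were not called. With the trend removed the mitosis list was also lower (median -0.10, camera adjusted p = 0.000661), but it did not pass with an estimated correlation (adjusted p = 0.321). An equal loss of all cell cycle transcripts would lower both alike, but the mitosis median lay 0.0578 above the replication median with the trend removed (95% bootstrap interval 0.0219 to 0.147). That interval resamples correlated genes and holds no variation between libraries. Per library, the mitosis minus replication median of deviations from the gene means was 0.0444 ± 0.00553 in CBR-470-1 and -0.0458 ± 0.0432 in DMSO (SD, n = 3 each), with no overlap. The DMSO mean leans on replicate 3, at -0.0954 against -0.0262 and -0.0158 in replicates 1 and 2. An exact test of 3 against 3 cannot go below p = 0.1. The contrast was chosen after replication had been seen called and mitosis not, so it does not decide against an equal loss. Fewer cycling cells, with an equal or an unequal loss of transcripts, stays open.

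GAGE12F and GAGE12G each fell from 3.94 ± 0.867 to 0.307 ± 0.332 TPM, yet the 13 GAGE rows summed to 50.1 ± 3.85 TPM in DMSO and 50.9 ± 9.72 TPM in CBR-470-1, a log2 ratio of 0.0233. The sum in CBR-470-1 rests on replicate 3, at 62.1 TPM against 46.3 and 44.4 TPM in the others, with GAGE12B at 18.3 TPM. Without that library the log2 ratio was -0.14, so the sums do not decide. Reads assigned differently among near-identical paralogs and a change of single copies cannot be told apart here.

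The real split gave 265 called genes, 13 2-fold calls and 8 lists, against at most 2, 2 and 6 in the other splits; 1 of the 10 splits, the real one, was as large in each case, and 10 splits are too few for a share under 0.05. Camera with its preset correlation passed the mitochondrially encoded list in 6 of the 9 other splits, the NRF2 list in 6, replication in 5 and cholesterol in 4. Every other split mixed the treatments unequally, so part of a treatment difference stays in it and the rest adds to its spread. Counts from the other splits are therefore not a rate of false calls. A leftover treatment difference does not account for the mitochondrially encoded list, which was not called in the real split (camera adjusted p = 0.596). Its estimated correlation was 0.80, against the preset 0.01. The mitosis list, not called either (camera adjusted p = 0.102, estimated correlation 0.37), passed in 3 of the 9 other splits. Passes at the preset correlation can thus reflect members that vary together.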
